A study of Mus musculus with 15 samples.

How the data were processed

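RNA of HT-22 cells was extracted with Trizol and sequenced after selection of poly(A) RNA with poly-T beads, per the labels' protocols. Those protocols name a pair of library kits with different RNA inputs and do not say which library was made with which kit. The values are whole-number counts of reads per gene in 1 table deposited by the authors, with a column per library, not normalized. The genome build is mm10, per the submitters' processing notes. The aligner, the counting tool and whether reads or read pairs were counted are not given in the sources used here. Between 69.6% and 84.1% of the counts from 1 to 19 in each library were even numbers. The table holds 49492 genes and 13 columns of counts, each matched to 1 of the 15 samples by its name. The 2 remaining LPS samples were not analysed here.

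Gene positions and transcript GC content came from GENCODE M21 on the same build, matched by symbol: 47240 symbols (95.4%) were found, and 42919 of these (90.9%) had the same chromosome, start, end and strand as in the count table. An exon of 10195 genes overlaps an exon of another gene, and such genes, with paralogs and pseudogenes, may share reads. The chi-square per degree of freedom over genes with a summed count of at least 20 was at least 6.90 in every pair of a group. Counts spread more than independent reads would in all groups, so that this value does not show separate replicates. Control 1, 3 and 4, control 2 and 5, vesicle 2 and 3, and vesicle 4 and 5 were close, with variance-to-mean ratios of at most 4.02 over mean counts of 20 to 200, against at least 8.24 in other control and vesicle pairs. Pairs of LPS libraries, whose ratio is nearly flat, may differ by little more than sampling noise. Each library counted as 1 replicate, and whether close libraries are technical replicates was not decided.

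CPM values are a library's counts scaled to its total count in the usual CPM unit and are given as mean ± SD over the libraries of a group. Fold changes came from edgeR's quasi-likelihood test (glmQLFit and glmQLFTest, edgeR 4.0.16, R 4.3.3) with TMM scaling, which can make them differ from ratios of CPM. All 13 libraries entered 1 fit with the group as the only term, after edgeR's default filter on low counts, which left 18358 genes. Tests were two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.484. The 32 gene lists were fixed before the data were examined and tested with camera (limma 3.58.1) on voom log2 CPM with a preset correlation of 0.01, adjusted over the lists. A list p in the text is camera's adjusted p unless named otherwise. Named genes were also chosen by a rule set before the data were examined. They are the 8 largest rises and falls per LPS comparison (6 in vesicles vs control) among called protein-coding genes with a mean of at least 2 CPM in 1 of the groups and no overlap between the groups' libraries, with every gene the series text names. To these the rule adds up to 4 members with the smallest adjusted p per list described, of which the text takes at most 2, and members given as a count of 5 or fewer or that went against their list. The rule was written for 5 LPS libraries and was applied to the 3 analysed.

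The test was tested on simulated data in which 200 genes were changed, 50 at each size. Control and vesicle counts were drawn with a spread estimated over both groups together, and LPS counts with that spread and added noise. In LPS vs control it recovered 12%, 30%, 72% and 94% of genes changed by 0.5, 1, 2 and 3 on the log2 scale, and also called 1809 unchanged genes of 17767 run. In simulations without any change the test called a median of 1690 genes in this comparison. A filter of at least 1 CPM in at least 5 libraries left a median of 78. Calls of unchanged genes thus depended on genes with low counts, and their cause was not tested apart. The counts of LPS libraries spread far more than counts of independent molecules. A further test was therefore added after seeing the data. Effective counts are the deposited counts divided by the lowest variance-to-mean ratio among the pairs of libraries of a group (41.3 in LPS, 3.27 in control, 3.15 in vesicle libraries) and rounded. On effective counts the same fit tested 15307 genes. In the simulation it called 3 unchanged genes of 11922 run and recovered 2%, 6%, 44% and 72% of the changed genes, so that a gene missed there is not shown to be unchanged. In vesicles vs control the planned test recovered 0%, 4%, 58% and 74%, with 0 unchanged genes of 17765 called. The simulated libraries held no close libraries and no outlying library. These values therefore do not give the rate of false calls in the real libraries. The noise of LPS libraries was simulated with a gamma-distributed number of reads per molecule whose shape was set on the share of zeros in LPS libraries alone. Simulated LPS libraries had a median lowest ratio of 48.1, above the measured 41.3. The values that chance and such noise allow came from 20 simulations without any change. A group without a count is given a floor of 3 effective counts over the group, which is 1.69 CPM in LPS, 0.0322 CPM in control and 0.0324 CPM in vesicle libraries.

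Alternatives set before the data were examined were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom with sample weights, no low-count filter, a stricter filter (at least 1 CPM in at least 5 libraries), only the groups compared, the replicate number as a block, a fold threshold of 1 on the log2 scale, library sizes without the top 50 genes, each library left out, and, for lists, an estimated correlation and fry. Splitting 5 LPS libraries into 2 and 3 was planned and could not be run with 3 libraries, so that splits into 1 and 2 were used instead. Effective counts, an offset for GC content and gene length (natural splines per library), and fits within sets of libraries were added after seeing the data. So was a fit in which close libraries, those of a pair with a ratio under 5, were summed and counted as 1, which left 2 control, 3 LPS and 3 vesicle replicates. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Results of 2 genes that the rule names are not reported here.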

Results

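Gene-level read counts were available from RNA sequencing of HT-22 cells, an immortalised mouse hippocampal neuronal line, in 3 groups. The groups were control cells, cells given lipopolysaccharide (LPS), the Gram-negative cell wall component sensed by Toll-like receptor 4, and cells given membrane vesicles of the probiotic bacterium Bifidobacterium lactis BL99. Of the 15 samples in the labels, 13 libraries were analysed: 5 control, 3 LPS and 5 vesicle libraries. LPS libraries 4 and 5 were not analysed here. The labels do not say whether the cells given vesicles were also given LPS, nor whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

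Total counts ranged from 56034353 to 69040610 in control, 22414660 to 27689266 in LPS and 43611478 to 66428188 in vesicle libraries. A count above 0 was found for 22425 to 23403 genes in control, 15561 to 16001 in LPS and 22124 to 23852 in vesicle libraries. Mitochondrial ribosomal RNA took 1.59% ± 0.0709 (SD, n = 3) of the counts in LPS libraries, against 0.0242% ± 0.00588 (SD, n = 5) in control and 0.0334% ± 0.00872 (SD, n = 5) in vesicle libraries. A single gene model, Gm10925, took 8.56% ± 0.205 of the counts in LPS libraries, against 0.524% ± 0.0882 in control and 0.621% ± 0.0928 in vesicle libraries. Between pairs of LPS libraries, the variance of gene counts was 41.3 to 43.2 times their mean and stayed nearly flat with expression. The ratio was 3.27 to 17.2 among control pairs and 3.15 to 49.7 among vesicle pairs, highest in pairs with vesicle 1. Counts were therefore also divided by each group's lowest ratio. These effective counts came to 542728 to 670442 per LPS library and to at least 13844914 in each of the other libraries. For the LPS comparisons, "rose" and "fell" are used below for single genes that passed both the planned test on the deposited counts and the same test on effective counts.

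**Figure D1:**
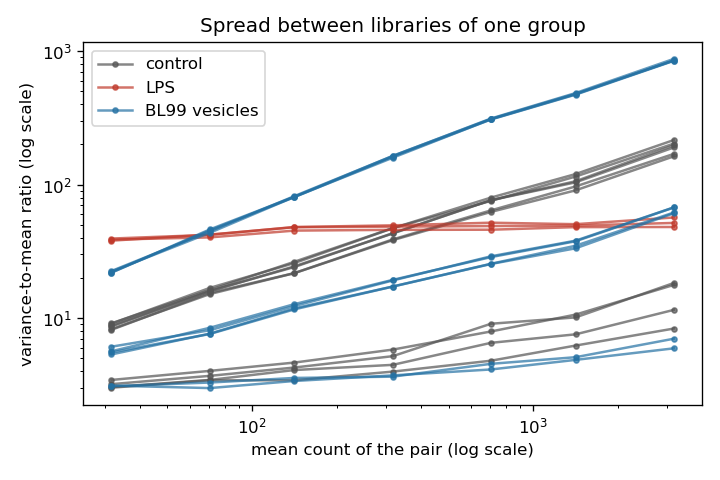
Variance-to-mean ratio of gene counts for each pair of libraries of one group (y axis, log scale) against the mean count of the genes (x axis, log scale); each line is 1 pair of libraries. LPS pairs stay nearly flat, with a ratio of 41.3 to 43.2 over mean counts of 20 to 200. Over these counts control pairs have 3.27 to 17.2 and vesicle pairs 3.15 to 49.7. The ratios of control and vesicle pairs are higher at the highest mean counts than at the lowest.

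The first comparison asked how the LPS libraries differed from those of control cells. LPS exposure and any batch shared by the LPS libraries alone cannot be told apart by this design. The test on effective counts addresses sampling noise only. Genes of cell division, RNA splicing and amino acid supply were lower in the LPS libraries, and genes of the cytosolic ribosome, the mitochondrial genome and cholesterol synthesis were higher. With an estimated correlation the calls of the mitochondrial and cholesterol lists held (adjusted p = 0.011 and 0.0018) and those of the others were lost (adjusted p = 0.30 to 0.66). Cdk1, the kinase that drives entry into mitosis (chromosome 10, 69336635 to 69352938), fell from 98.9 ± 5.89 CPM (SD, n = 5) to 7.22 ± 0.814 CPM (SD, n = 3), a log2 fold change of -3.48 ± 0.16 (SE). Stard4, a sterol transport protein (chromosome 18, 33199355 to 33213862), rose from 26.0 ± 7.04 to 170 ± 19.2 CPM, a log2 fold change of 3.01 ± 0.23. Cflar, an inhibitor of caspase-8 activation (chromosome 1, 58711508 to 58758884), rose from 68.3 ± 2.96 to 340 ± 12.7 CPM, a log2 fold change of 2.61 ± 0.20.

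With the planned edgeR quasi-likelihood test on the deposited counts, 3293 of 18358 genes were higher and 5294 were lower in LPS than in control libraries. In 20 simulations no gene differed and the LPS libraries carried noise modelled on that between them. That test still called a median of 1690 genes, of which 1620 were lower. The simulated noise was larger than measured, with a median lowest variance-to-mean ratio of 48.1 against 41.3 between LPS libraries. The number called from noise may therefore be too high. On effective counts, 2135 of 15307 genes were higher and 2812 lower, with a simulated median of 0, and 2132 higher and 2756 lower genes were called by both tests. With close libraries summed to 2 control, 3 LPS and 3 vesicle replicates, 1013 genes were higher and 2506 lower, and of the genes named here Bcl2, Tgfb2, Map3k7, Ikbkb and Il18r1 lost their call.

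The 8 largest rises were in Krt4, Rptn, Myh1, Gnat3, Myh8, Calml3, Tnnt3 and Ccdc172. Krt4, a keratin of squamous epithelium (chromosome 15, 101918536 to 101924735), rose from 0.0128 ± 0.0286 CPM (SD, n = 5) to 31.9 ± 2.16 CPM (SD, n = 3), a log2 fold change of 11.28 ± 0.81 (SE) with an adjusted p of 2.6e-07. Myh8, the perinatal skeletal myosin heavy chain (chromosome 11, 67277124 to 67308634), rose from 0.0745 ± 0.0652 to 62.9 ± 3.10 CPM, a log2 fold change of 10 ± 0.83. Rptn, an epidermal protein, rose to 17.6 ± 1.03 CPM, Myh1, an adult myosin heavy chain, to 29.1 ± 3.46 CPM, the fast muscle troponin T gene Tnnt3 to 24.2 ± 2.05 CPM, and Ccdc172 to 9.74 ± 2.14 CPM, each from under 0.1 CPM. Gnat3 and Calml3 reached 2.47 ± 1.83 and 4.36 ± 1.28 CPM but were too low for the test on effective counts. Myosin paralogs are similar in sequence and their reads could be split between them. Among the largest falls, Cyp4f13, Dcp1b, Dyrk4, Mutyh and Chchd10 had no count in any LPS library. Set against a floor of 3 effective counts over the group, which is 1.69 CPM, Cyp4f13 was at least 3.32-fold lower and Chchd10 at least 1.54-fold lower. Nid2, Klhl36 and Ogdhl, also without a count in LPS libraries and at 3.42, 2.79 and 2.48 CPM in control libraries, did not pass the test on effective counts. Such floors cover counting error only.

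Camera called 4 lists lower, which were G2/M and mitosis, S phase, RNA splicing and ATF4 genes. Of 39 tested genes of G2/M and mitosis, 26 were lower and 3 higher (26 and 3 adjusted over the list alone; 23 and 2 on effective counts; camera adjusted p = 0.0038). Bub1b, a spindle checkpoint kinase, fell from 292 ± 31.7 to 56.7 ± 11.3 CPM, while Mki67, Cenpf and Birc5 were the 3 higher members. Of 37 genes of DNA replication and S phase, 20 were lower and 3 higher (21 and 3 adjusted over the list alone; 17 and 3 on effective counts; adjusted p = 0.0055). Mcm2, a subunit of the replicative helicase, fell from 481 ± 30.9 to 99.2 ± 4.12 CPM, and Lig1, which joins Okazaki fragments, from 453 ± 87.2 to 108 ± 9.81 CPM. The higher members were Rfc4, Rfc5 and E2f1. Of 37 RNA splicing factors, 24 were lower and 2 higher, Srsf3 and Hnrnpa1 (24 and 2 adjusted over the list alone; 23 and 2 on effective counts; adjusted p = 0.00055). Prpf8, the core protein of the spliceosome, fell from 323 ± 15.5 to 29.6 ± 9.60 CPM, a log2 fold change of -3.15 ± 0.20, and Srsf5 from 485 ± 16.4 to 97.2 ± 9.37 CPM. Of 37 ATF4 and amino acid response genes, 28 were lower and 1, Atf5, was higher (28 and 1 adjusted over the list alone; 25 and 1 on effective counts; adjusted p = 0.00013). Yars, the tyrosyl-tRNA synthetase, fell from 265 ± 8.07 to 39.1 ± 3.62 CPM and Cars, the cysteinyl-tRNA synthetase, from 322 ± 44.5 to 78.3 ± 17.0 CPM. With an estimated correlation these calls were lost, with an adjusted p = 0.59 for G2/M and mitosis, 0.30 for S phase, 0.66 for splicing factors and 0.59 for ATF4 genes. The same LPS libraries held 1.59% of their counts in mitochondrial ribosomal RNA.

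Cytosolic ribosomal protein genes were higher as a group, with 61 of 78 higher and 2 lower, Rpl23a and Rpl38 (63 and 2 adjusted over the list alone; 55 and 2 on effective counts; camera adjusted p = 5.4e-26, and adjusted p = 0.50 with an estimated correlation). Rplp1 rose from 1030 ± 175 to 5360 ± 407 CPM and Rps3a1 from 693 ± 88.2 to 3580 ± 233 CPM, values that are uncertain because ribosomal protein genes have many processed pseudogenes. Of 25 cholesterol biosynthesis genes, 17 were higher and 0 lower (20 and 0 adjusted over the list alone; 15 and 0 of 24 on effective counts; adjusted p = 3.8e-08, and adjusted p = 0.0018 with an estimated correlation). Cyp51, the lanosterol demethylase, rose from 54.5 ± 1.5 to 170 ± 15.4 CPM. Of 11 mitochondrially encoded protein genes, 7 were higher and 0 lower (9 and 0 adjusted over the list alone; 5 and 0 of 9 on effective counts; adjusted p = 5e-06, and adjusted p = 0.011 with an estimated correlation). mt-Cytb rose from 2510 ± 211 to 8790 ± 474 CPM and mt-Nd4, whose exon overlaps mt-Nd4l, from 1730 ± 130 to 5350 ± 517 CPM, beside the higher mitochondrial ribosomal RNA share of the same libraries. Of 12 fibroblast and mesenchymal markers, 7 were higher and 0 lower (7 and 0 adjusted over the list alone; 7 and 0 of 11 on effective counts; adjusted p = 0.00052, and adjusted p = 0.19 with an estimated correlation). Col1a2, a chain of type I collagen, rose from 23.0 ± 11.3 to 110 ± 3.84 CPM and Pdgfrb from 14.5 ± 4.10 to 37.1 ± 8.83 CPM. In the same LPS libraries, 15 of 35 squamous epithelium and 10 of 27 skeletal muscle markers were at 1 CPM or more and at least 10 times their mean in either other group. Of 21 TGF-beta response genes, 9 were higher, Ltbp2 and Tgfb2 among them, and 1, Id3, was lower (9 and 1 adjusted over the list alone; 5 and 1 of 20 on effective counts; adjusted p = 0.02, and adjusted p = 0.66 with an estimated correlation). Of 32 genes of the apoptosis machinery, 11 were higher and 5 lower (11 and 5 adjusted over the list alone; 10 and 5 on effective counts; adjusted p = 0.045, and adjusted p = 0.19 with an estimated correlation). The inhibitors Cflar and Xiap were among the higher members, and Xiap rose from 59.0 ± 4.01 to 158 ± 22.8 CPM. The lower members were Bax and Apaf1, which promote apoptosis, with Cycs, Casp2 and Aifm1. The calls of the TGF-beta and apoptosis lists were lost without LPS library 1 and without LPS library 3, and that of apoptosis also without control 5. On effective counts the TGF-beta list had an adjusted p = 0.19 and the apoptosis list an adjusted p = 0.47, and with the GC and length offset the apoptosis list had an adjusted p = 0.095.

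Inflammatory lists did not pass camera. Of 32 NF-kB responsive genes, 5 were higher, Tnfaip3, Tnfaip2, Vcam1, Csf2 and Zc3h12a, and 9 lower (5 and 9 adjusted over the list alone; 4 and 5 of 30 on effective counts; adjusted p = 0.60); the list's median log2 fold change was 0.10 and its mean -0.41. Lcn2 fell from 24.2 ± 4.90 to 4.92 ± 2.34 CPM and Nfkb2, a subunit of NF-kB, from 306 ± 20.3 to 96.6 ± 6.96 CPM. Of 36 interferon-stimulated genes, 2 were higher, Ifit2 and Ifit3, and 11 lower (1 and 9 adjusted over the list alone; 1 and 4 of 35 on effective counts; adjusted p = 0.26). Trim25 fell from 55.7 ± 8.11 to 10.1 ± 5.84 CPM, and Mx2 had no count in LPS libraries, against 2.63 ± 0.958 CPM in control libraries, without passing the test on effective counts. Of 19 TLR4 receptor and adaptor genes, 5 were higher, Irak1, Irak2, Traf6, Map3k7 and Sigirr, and 2 lower, Ikbkb and Chuk (5 and 2 adjusted over the list alone; 4 and 2 on effective counts; adjusted p = 0.26). Of 9 IL-33 and IL-1 family genes, 2 were higher, Il1r1 and Il18r1, and 3 lower, Il1a, Il18 and Il1rn (2 and 3 adjusted over the list alone; 2 and 0 of 7 on effective counts; adjusted p = 0.40). Il1r1 rose from 13.6 ± 3.12 to 36.7 ± 3.33 CPM and Il18r1 from 0.153 ± 0.184 to 4.53 ± 4.38 CPM. Of 31 p53 target genes, 5 were higher and 7 lower in every count (adjusted p = 0.60). Ccng1 rose from 25.9 ± 5.16 to 123 ± 13.6 CPM and Perp from 25.5 ± 5.90 to 67.4 ± 8 CPM. Of 28 FoxO family and FoxO target genes, 6 were higher and 6 lower (6 and 6 adjusted over the list alone; 4 and 3 of 27 on effective counts; adjusted p = 0.24). Sesn3 rose from 27.7 ± 11.3 to 117 ± 9.27 CPM and Trib1 from 9.85 ± 1.70 to 36.0 ± 8.17 CPM.

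The next comparison set the vesicle group against the LPS group. Here too, a batch shared by the LPS libraries alone cannot be told apart from the treatments. Cell division, splicing and amino acid response genes were higher in the vesicle libraries and ribosomal, mitochondrial and cholesterol genes lower. With an estimated correlation the call of the cholesterol list held (adjusted p = 0.0011) and those of the others were lost (adjusted p = 0.063 to 0.45). Cdk1 was at 92.5 ± 19 CPM (SD, n = 5) in vesicle libraries, a rise of 3.51 ± 0.16 (SE) on the log2 scale from the LPS libraries. Srsf5, a splicing regulator (chromosome 12, 80945504 to 80950507), rose to 745 ± 62.4 CPM, a log2 fold change of 2.79 ± 0.14, and Hmmr, a spindle assembly protein (chromosome 11, 40701395 to 40733422), from 43.5 ± 14.6 to 307 ± 70.6 CPM, a log2 fold change of 2.64 ± 0.21. Stard4 fell to 24.1 ± 7.68 CPM, a log2 fold change of -3.00 ± 0.23, and Sod1, the cytosolic superoxide dismutase (chromosome 16, 90220742 to 90226322), from 659 ± 20.8 to 205 ± 23.1 CPM, a log2 fold change of -1.79 ± 0.19.

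The planned edgeR test called 5705 of 18358 genes higher and 3435 lower in vesicle than in LPS libraries. In the simulations without any difference, whose LPS noise was larger than measured, it called a median of 1706 genes, of which 1630 were higher. On effective counts, 3192 of 15307 genes were higher and 2234 lower, with a simulated median of 0, and 3099 higher and 2230 lower genes were called by both tests. With close libraries summed, 4083 were higher and 1746 lower, and Il33 lost its call.

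**Figure D2:**
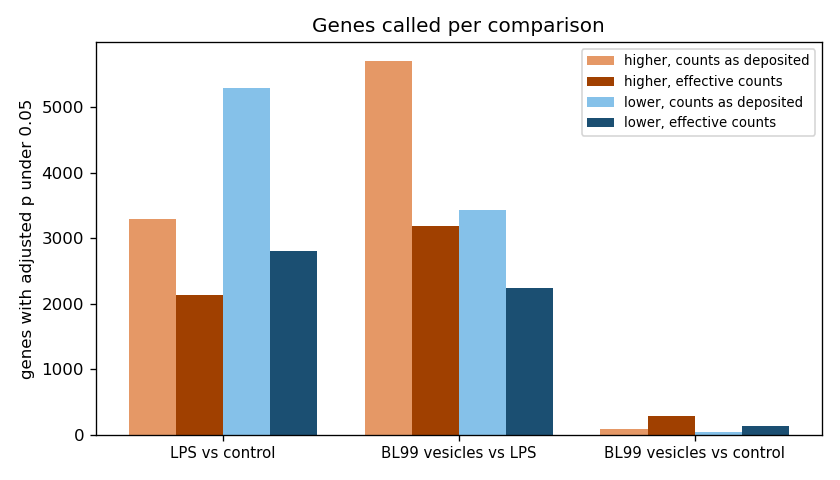
Number of genes called (y axis) in each comparison, higher and lower, with edgeR's quasi-likelihood test on the deposited counts (light bars) and on effective counts (dark bars). LPS vs control has 3293 higher and 5294 lower genes on deposited counts and 2135 and 2812 on effective counts, against 83 and 39, and 290 and 129, in vesicles vs control.

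Rptn, Tnni2, Krt4, Tnnt3 and Myh8 were among the largest falls. Rptn and the fast muscle troponin I gene Tnni2 had no count in any vesicle library and were at least 544-fold and at least 265-fold lower than in LPS libraries, against a floor of 3 effective counts over the group. Krt4 fell to 0.0131 ± 0.0180 CPM and Myh8 to 0.136 ± 0.135 CPM (SD, n = 5). Calml3, Igfbp5 and Dmkn, at 4.36 ± 1.28, 5.70 ± 0.401 and 5.55 ± 0.518 CPM in LPS libraries and at group means of at most 0.00667 CPM in vesicle libraries, were too low for the test on effective counts. Among the largest rises, from 0 counts in all LPS libraries, Cyp4f13 was at least 3.38-fold and Dyrk4 at least 2.49-fold higher. Il17f, Mss51, Taf9b, Tbkbp1 and Nid2 did not pass on effective counts, and Slc8a2 was too low for that test. Each was highest in vesicle library 1, where Il17f was at 23.0 CPM against at most 0.563 CPM in the other vesicle libraries and Nid2 at 10.8 CPM against at most 3.76 CPM. Slc8a2 lost its call without any 1 of the LPS libraries.

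Of 39 genes of G2/M and mitosis, 27 were higher and 2 lower, Cenpf and Birc5 (28 and 2 adjusted over the list alone; 27 and 2 on effective counts; camera adjusted p = 0.00029, and adjusted p = 0.40 with an estimated correlation). Of 37 genes of DNA replication and S phase, 21 were higher and 4 lower, Rfc2, Rfc4, Rfc5 and E2f1, in every count (adjusted p = 0.0059, and adjusted p = 0.32 with an estimated correlation). Ccne2, a cyclin of S phase entry, rose from 18.4 ± 1.81 to 185 ± 40.9 CPM and Mcm2 to 371 ± 88.1 CPM. Of 37 splicing factors, 29 were higher and 1, Srsf3, was lower (29 and 1 adjusted over the list alone; 27 and 1 on effective counts; adjusted p = 1e-06, and adjusted p = 0.45 with an estimated correlation). Rbm39 rose from 322 ± 37.9 to 1700 ± 302 CPM. Of 37 ATF4 and amino acid response genes, 25 were higher and 1, Atf5, was lower (26 and 1 adjusted over the list alone; 26 and 0 on effective counts; adjusted p = 0.00021, and adjusted p = 0.45 with an estimated correlation). Eprs, the glutamyl-prolyl-tRNA synthetase, rose from 314 ± 3.47 to 1660 ± 610 CPM and Yars to 195 ± 61.5 CPM. In vesicle 1 the list median on the log2 scale, relative to the mean of all libraries, was -0.14 for G2/M genes against 0.38 to 0.51 in vesicles 2 to 5, 0.62 for S phase against 0.10 to 0.17, and 0.99 for splicing factors against 0.31 to 0.35.

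Ribosomal protein genes were lower, 64 of 78, with only Rpl38 higher (66 and 1 adjusted over the list alone; 58 and 1 on effective counts; camera adjusted p = 1.3e-27, and adjusted p = 0.40 with an estimated correlation). Rplp1 fell to 790 ± 87.5 CPM and Rpl9 from 770 ± 61.1 to 152 ± 17.0 CPM. Of 25 cholesterol biosynthesis genes, 19 were lower and 0 higher (19 and 0 adjusted over the list alone; 17 and 0 of 24 on effective counts; adjusted p = 3.7e-09, and adjusted p = 0.0011 with an estimated correlation). Cyp51 fell to 50.1 ± 8.44 CPM. Of 11 mitochondrially encoded protein genes, 7 were lower and 0 higher (8 and 0 adjusted over the list alone; 4 and 0 of 9 on effective counts; adjusted p = 0.00031, and adjusted p = 0.063 with an estimated correlation). mt-Cytb fell to 3540 ± 726 CPM, beside a mitochondrial ribosomal RNA share of 0.0334%. Of 61 nuclear genes of oxidative phosphorylation, 26 were lower and 9 higher (26 and 10 adjusted over the list alone; 20 and 11 on effective counts; adjusted p = 0.00029, and adjusted p = 0.45 with an estimated correlation). Ndufb10, of complex I, fell from 183 ± 13.2 to 42.7 ± 9.88 CPM and Cox4i1, of complex IV, from 350 ± 8.78 to 144 ± 8.83 CPM. Of 36 NRF2 and antioxidant genes, 15 were lower and 8 higher (15 and 8 adjusted over the list alone; 12 and 8 on effective counts; adjusted p = 0.0059, and adjusted p = 0.45 with an estimated correlation). Sod1 was among the lower ones, and Txnrd1, the cytosolic thioredoxin reductase, rose from 100 ± 20.2 to 382 ± 30.9 CPM. Fibroblast and mesenchymal markers were lower in 7 of 12 (8 adjusted over the list alone; 7 of 11 on effective counts; adjusted p = 0.00031, and adjusted p = 0.19 with an estimated correlation). Col1a2 fell to 13.4 ± 5.29 CPM and Pdgfrb to 12.4 ± 3.32 CPM. TGF-beta response genes were lower in 7 of 21, with Tgfbr1 higher (7 and 1 adjusted over the list alone; 5 and 1 of 20 on effective counts; adjusted p = 0.033, and adjusted p = 0.52 with an estimated correlation). Of 32 apoptosis genes, 11 were lower and 5 higher, Bax, Apaf1, Casp2, Casp8 and Aifm1 (11 and 6 adjusted over the list alone; 9 and 6 on effective counts; adjusted p = 0.041, and adjusted p = 0.19 with an estimated correlation). Cflar fell to 88.0 ± 13.2 CPM. In vesicle 1 the list median on the log2 scale, relative to the mean of all libraries, was 0.40 for ribosomal protein genes against -0.59 to -0.43 in vesicles 2 to 5, -0.70 for oxidative phosphorylation against -0.20 to -0.03, and 0.86 for TGF-beta genes against -0.36 to -0.20. Without LPS library 1, and without LPS library 3, the TGF-beta and apoptosis calls were lost. On effective counts 4 lists lost their call, with an adjusted p = 0.11 for oxidative phosphorylation, 0.25 for NRF2, 0.23 for TGF-beta and 0.45 for apoptosis genes; with the GC and length offset the last 2 had an adjusted p = 0.10 and 0.086.

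Inflammatory lists did not pass camera here either. Of 32 NF-kB responsive genes, 8 were higher and 3 lower, Tnfaip2, Ccl7 and Zc3h12a (8 and 3 adjusted over the list alone; 5 and 3 of 30 on effective counts; adjusted p = 0.66). Lcn2 rose to 37.3 ± 14.3 CPM and Tnfaip2 fell from 56.7 ± 14.9 to 6.67 ± 3.03 CPM. Of 36 interferon-stimulated genes, 10 were higher and 0 lower (9 and 0 adjusted over the list alone; 3 and 0 of 35 on effective counts; adjusted p = 0.39). Trim25 rose to 42.5 ± 14.2 CPM. The interferon list's median on the log2 scale, relative to the mean of all libraries, was -1.39 in vesicle 1, below the -1 to -0.52 of the LPS libraries, and 0.15 to 0.65 in vesicles 2 to 5. Of 9 IL-33 and IL-1 family genes, 3 were higher, Il1rap, Il1a and Il18, and 4 lower, Il33, Il1rl1, Il1r1 and Il18r1 (3 and 4 adjusted over the list alone; 0 and 3 of 7 on effective counts; adjusted p = 0.35). Of 19 TLR4 receptor and adaptor genes, 3 were higher, Tab2, Ikbkb and Chuk, and 4 lower, Irak1, Irak2, Map3k7 and Sigirr (3 and 4 adjusted over the list alone; 3 and 2 on effective counts; adjusted p = 0.35). Of 31 p53 target genes, 7 were higher and 4 lower, Ccng1, Zmat3, Perp and Ei24, in every count (adjusted p = 0.69). Of 28 FoxO genes, 6 were higher and 4 lower, Foxo4, Trib1, Sesn3 and Trim63 (6 and 4 adjusted over the list alone; 5 and 3 of 27 on effective counts; adjusted p = 0.35); their median log2 fold change of 0.60 and mean of 0.33 were above 0 while camera's direction was down. Relative to the mean of all libraries the FoxO list's median was 0.96 in vesicle 1 and -0.40 to -0.19 in vesicles 2 to 5, below the 0 to 0.17 of the LPS libraries.

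Most genes called in both LPS comparisons went in opposite directions: 2748 were higher in LPS than in control and lower in vesicles than in LPS, 4750 were lower and then higher, and 3 went the same way in both. Both comparisons use the same LPS libraries, which alone gives opposite calls. In the simulations without any difference, a median of 1386 genes (1330 to 1500) was called in opposite directions, and independent lists of these sizes would share 2261. Across genes, which are not independent replicates, the Pearson correlation of the log2 fold changes was -0.971, against -0.981 in the simulations, and their covariance was -7.064 against -4.561. With different LPS libraries in each comparison, 4167 to 4479 genes were opposite over 6 ways of splitting the 3 libraries, against a simulated median of 45.5, with a correlation of -0.568 to -0.542 against -0.312 and a covariance of -5.578 to -5.496 against -2.481. A comparison with 1 LPS library takes its spread from the other groups, and part of the excess may come from the shared libraries. The simulations held no difference of the LPS libraries, and any difference common to all 3 of them gives opposite calls in every split. Vesicle and control libraries differed in only 122 genes by the planned test. The excess therefore does not tell whether vesicles reversed a change made by LPS. On effective counts 4226 genes were opposite, against a simulated median of 0, and with close libraries summed 3323 were opposite.

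Of the 13 genes that the series text names, 10 could be tested. They were chosen by the study on these samples, so that their counts are no independent evidence of a direction. In LPS against control libraries 2 were higher and 4 lower (2 and 4 adjusted over the list alone, 2 and 3 on effective counts). In vesicle against LPS libraries 4 were higher and 2 lower (4 and 2 adjusted over the list alone, 3 and 0 on effective counts). In vesicle against control libraries the planned edgeR test called 0. Il33 and others were called with the sets of libraries as a term, where p-values measure only the small spread between close libraries. Trp53, which encodes p53 (chromosome 11, 69580359 to 69591873), fell from 81.9 ± 30 CPM (SD, n = 5) in control to 19.9 ± 11.6 CPM (SD, n = 3) in LPS libraries (edgeR adjusted p = 0.0033) and stood at 86.5 ± 15.3 CPM (SD, n = 5) in vesicle libraries (adjusted p = 0.0013 against LPS). The NF-kB subunit Nfkb1 (chromosome 3, 135584655 to 135691547) was at 85.9 ± 25.3, 32.9 ± 6.92 and 98.0 ± 24.2 CPM in control, LPS and vesicle libraries, and Rela (chromosome 19, 5637483 to 5648130) at 70.7 ± 12.5, 26.2 ± 1.59 and 56.4 ± 10.9 CPM. Both fell in LPS libraries (adjusted p = 0.0081 and 0.00033) and rose in vesicle against LPS libraries (adjusted p = 0.0015 and 0.0011). Bcl2, an inhibitor of apoptosis (chromosome 1, 106538178 to 106714274), rose from 23.7 ± 2.94 to 32.9 ± 3.57 CPM (adjusted p = 0.0015) and was at 28.7 ± 5.41 CPM in vesicle libraries, not distinguishable from LPS (adjusted p = 0.075).

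Il33, an alarmin cytokine (chromosome 19, 29925114 to 29960718), was at 0.951 ± 0.220 CPM in control and 0.380 ± 0.0975 CPM in vesicle libraries (SD, n = 5). It was at 0.345, 1.96 and 3.54 CPM in the LPS libraries, near the floor of 1.69 CPM that holds for the LPS group as a whole. The floor of a single LPS library is higher. Vesicle against LPS libraries gave a log2 fold change of -2.46 ± 0.61 (SE), which passed on deposited counts (adjusted p = 0.0045) and not on effective counts (adjusted p = 0.087). Foxo6, at 2.76 ± 1.69, 2.25 ± 2.34 and 1.27 ± 0.261 CPM in control, LPS and vesicle libraries, Foxo1, at 8.23 ± 2.59, 8.55 ± 4.72 and 7.33 ± 1.04 CPM, and Casp9, at 6.92 ± 2.73, 3.15 ± 0.259 and 5.40 ± 2.34 CPM, were not called by the planned test in any comparison. Il6 had 0 counts in LPS libraries, and its 1.11 ± 1.07 CPM in control and 1.51 ± 0.781 CPM in vesicle libraries lie under the 1.69 CPM floor of the LPS group, so that a difference was not detectable at this depth, although the test on deposited counts called it. Il10, Tnf and Il1b were too low to be tested.

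**Figure D3:**
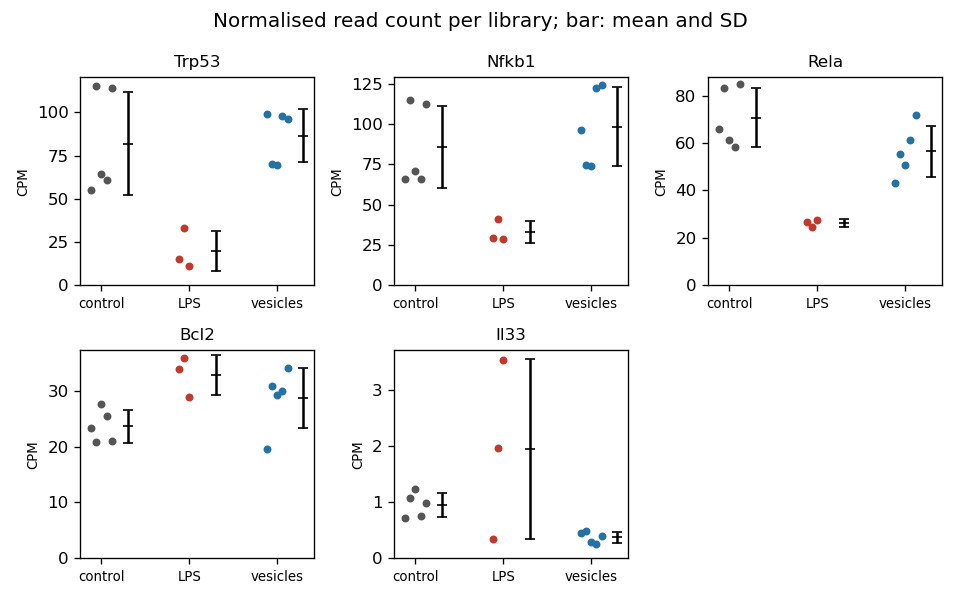
Normalised read count in CPM (y axis) of 5 genes in control, LPS and vesicle libraries (x axis); each point is 1 library and the bar beside the points is the mean and SD. Trp53, Nfkb1 and Rela are lowest in LPS libraries, and Il33 ranges from 0.345 to 3.54 CPM among the 3 LPS libraries.

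The last comparison placed the vesicle group against control cells. The planned test called 122 genes, among them the splicing factors Srsf5, Srsf10 and Pnisr and the mitosis genes Hmmr and Kif11, which were higher, and Ndufb10 of respiratory complex I, which was lower in vesicle libraries. Ccne2 (chromosome 4, 11191351 to 11204779) rose from 69.3 ± 6 to 185 ± 40.9 CPM (SD, n = 5 and n = 5), a log2 fold change of 1.62 ± 0.22 (SE) with an adjusted p of 0.0063. U2surp, a U2 snRNP-associated protein (chromosome 9, 95456898 to 95511996), rose from 201 ± 11.3 to 484 ± 175 CPM, a log2 fold change of 1.51 ± 0.28, and Pnisr, a splicing-associated protein (chromosome 4, 21847583 to 21876475), from 241 ± 21.6 to 449 ± 18.8 CPM, a log2 fold change of 1.06 ± 0.13. Nenf, a secreted neurotrophic factor (chromosome 1, 191306789 to 191318194), fell from 12.2 ± 3.27 to 2.21 ± 1.05 CPM, a log2 fold change of -2.36 ± 0.40.

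The edgeR test called 83 genes higher and 39 lower of 18358, and effective counts called 290 and 129 of 15307, with every one of the 122 planned calls among them in the same direction. Simulations without any difference gave a median of 0, but they held no close libraries and no library apart from its group, as vesicle 1 is. Of simulated genes changed by 1 on the log2 scale the planned test recovered 4%. DESeq2 called 558 higher and 320 lower genes and limma-voom with sample weights 3176 and 3299. With close libraries summed to 2 control and 3 vesicle replicates, edgeR called 0 genes, with 466 of 19229 at an unadjusted p under the threshold and a smallest adjusted p of 1, so that none of the 122 calls held with these fewer replicates. Leaving out any 1 of the 10 control and vesicle libraries moved the number called from 122 by over 1.5 times, from 32 without control 1 to 882 without vesicle 1. With an offset for GC content and gene length, 1 of the 122 genes stayed past the threshold; all 122 kept their sign, and their median absolute log2 fold change went from 0.90 to 0.59. The higher genes had a median transcript GC content of 40.7% and the lower genes 57.1%, against 49.9% for all tested genes.

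Other rises were in 3830403N18Rik, Slfn9, Phip and Zfp943, with log2 fold changes of 1.40 ± 0.23, 1.38 ± 0.25, 1.37 ± 0.26 and 1.23 ± 0.24. Other falls were in Twist2, a mesenchymal transcription factor, from 18.0 ± 9.64 to 3.39 ± 0.831 CPM, Glrx5, a mitochondrial iron-sulphur protein, from 35.5 ± 23.0 to 8.13 ± 1.60 CPM, Sdhaf1, an assembly factor of complex II, from 16.7 ± 3.99 to 4.10 ± 1.85 CPM, and E130208F15Rik, whose exon overlaps Sdhaf1, from 16.7 ± 3.98 to 4.01 ± 1.79 CPM. The agouti gene, symbol a (chromosome 2, 154791402 to 155051012), fell from 91.3 ± 39.3 to 5.59 ± 1.38 CPM. Its annotated exons share the strand with an exon of Raly, so that reads of these genes cannot be told apart.

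Of 37 splicing factors, Srsf5, Srsf10 and Pnisr were higher and none lower (13 and 1 adjusted over the list alone; camera adjusted p = 7.2e-09, and adjusted p = 0.42 with an estimated correlation). Srsf10 rose from 279 ± 13.4 to 468 ± 51.3 CPM. Of 61 nuclear genes of oxidative phosphorylation, 1 was lower, Ndufb10, from 70.2 ± 7.82 to 42.7 ± 9.88 CPM (1 adjusted over the list alone; adjusted p = 1.3e-12, and adjusted p = 0.22 with an estimated correlation). Of 11 mitochondrially encoded protein genes, mt-Cytb and mt-Nd4l were higher (4 adjusted over the list alone; adjusted p = 0.00029, and adjusted p = 0.088 with an estimated correlation). With the GC and length offset this list was no longer called (adjusted p = 0.41), and its direction turned downward. Of 39 G2/M genes, Hmmr and Kif11 were higher (10 adjusted over the list alone; adjusted p = 0.00045, and adjusted p = 0.42 with an estimated correlation), a call that the offset ended. The NRF2 list was lower, with Taldo1 its called member (3 adjusted over the list alone; adjusted p = 8.8e-05, and adjusted p = 0.23 with an estimated correlation), as was cholesterol biosynthesis, with 1 called member (4 adjusted over the list alone; adjusted p = 0.016, and adjusted p = 0.13 with an estimated correlation). Ribosomal protein genes (adjusted p = 0.0037), extracellular matrix genes (adjusted p = 0.0047) and unfolded protein response chaperones (adjusted p = 0.041) passed camera without a called member, the last upward and the others downward, with an adjusted p = 0.92, 0.13 and 0.45 with an estimated correlation. The ribosomal call was lost on effective counts (adjusted p = 0.11) and with the offset (adjusted p = 0.47), and with close libraries summed those of ribosomal (adjusted p = 0.60) and chaperone genes (adjusted p = 0.065) were lost. Vesicle 1 stood apart from the other vesicle libraries in several of these lists. On the log2 scale, relative to the mean of all libraries, its list median was 0.99 for splicing factors against 0.31 to 0.35 in vesicles 2 to 5, -0.70 for oxidative phosphorylation against -0.20 to -0.03, -0.14 for G2/M genes against 0.38 to 0.51, and 0.40 for ribosomal protein genes against -0.59 to -0.43. Ndufb10 was at 25.7 CPM in vesicle 1 and at 43.8 to 50.9 CPM in the other vesicle libraries. Without vesicle 1 all 9 lists were still called by camera in the same direction. The NF-kB, interferon, TLR4, IL-33, p53 and FoxO lists had 0 called members each, with 1 p53 target higher and 1 lower when adjusted over the list alone, and camera adjusted p from 0.38 to 0.89. At an unadjusted p under the same threshold edgeR called 2259 of all 18358 genes, and DESeq2 called 878 after adjustment.

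Control and vesicle libraries also fell into 2 sets across the groups, control 1, 3 and 4 with vesicle 2 and 3, and control 2 and 5 with vesicle 4 and 5, on the first component of their deviations from the group means, which held 53.6% of that variance. Vesicle 1 was left out of the sets. Within the first set 3414 genes were higher and 3293 lower in vesicle libraries, and within the second 3525 and 4031, each with all 122 planned calls. Of 16773 genes tested in both, 1892 were higher and 1618 lower in both sets and 562 were opposite, against 702 and 771.5 for independent lists. The sets were drawn from the same counts and are no groups of the study. Libraries of 1 group within a set are the close ones, so that p-values within sets and with a set term measure only the small spread between them.

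Several lists had called members within the sets, and for some the counts went opposite ways. Of 36 interferon-stimulated genes, 3 were higher and 15 lower in vesicle libraries of the first set, and 18 higher and 2 lower in the second. Of 37 ATF4 and amino acid response genes, 18 were higher and 3 lower in the first set, and 5 and 23 in the second. FoxO genes were 3 higher and 10 lower of 27, then 10 and 6. NF-kB genes were 2 higher and 11 lower of 32, then 6 and 10 of 31, and TLR4 genes 6 and 1, then 5 and 7 of 19. IL-33 and IL-1 family genes were 0 higher and 2 lower, then 2 and 4 of 8, and p53 targets 8 and 7, then 11 and 10 of 31. Splicing factors were 24 higher and 4 lower, then 15 and 14 of 37. Counts leaned the same way in both sets for G2/M genes, 19 higher and 2 lower, then 22 and 2 of 39, for oxidative phosphorylation, 0 and 36, then 1 and 34 of 61, and for ribosomal protein genes, 0 and 63, then 2 and 57 of 78. Log2 fold changes followed GC content across genes in both sets (Spearman rho -0.48 and -0.32; genes are not independent replicates). With the set as a term, 18 splicing factors were higher and 7 lower, and 9 and 9 with the GC and length offset added; for G2/M genes the counts went from 19 and 0 to 13 and 1 and the median log2 fold change from 0.22 to 0.07. The differences between the sets were not tested.

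With the set as a term and vesicle 1 left out, the genes of the series text that edgeR called between vesicle and control libraries included Il33, at a log2 fold change of -1.36 ± 0.29 (SE; adjusted p = 0.0029), which was lower within both sets (adjusted p = 0.046 and 0.0024). Bcl2 was higher by 0.44 ± 0.081 (adjusted p = 0.0013) and Nfkb1 by 0.16 ± 0.048 (adjusted p = 0.021), while Rela, at -0.24 ± 0.068 (adjusted p = 0.016), and Foxo6, at -0.80 ± 0.26 (adjusted p = 0.032), were lower. With the GC and length offset added, Il33 (adjusted p = 0.0014), Nfkb1 (0.020) and Bcl2 (0.044) were still called, and Rela (0.87) and Foxo6 (0.25) were not. Trp53 was not called with the term (adjusted p = 0.76), being higher within the first set and lower within the second. With close libraries summed, edgeR called 0 genes between vesicle and control libraries, so that these calls rest on the spread between close libraries.

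Opposite-strand neighbours share exon sequence with Myh1, Nid2, Chchd10, Nfkb2, Yars, Cars, Cyp51, Lig1, Ltbp2, Tgfb2, Bcl2, Foxo1, Casp9, Ei24, Gadd45a, Cox4i1 and Ccne2, and Rptn overlaps Gm37857 on its own strand. Whether the counts separate strands is not given in the sources used here, so the values of these genes may include reads of their neighbours. Positions are those of GENCODE M21 on mm10, and counts cover exons of the whole gene.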

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

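The tests of GC content and of vesicle 1 alone, with the fits on effective counts and within sets of libraries, were chosen after the result was seen; the splits of the libraries were planned.

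In each control or vesicle group of 5, the gap from the highest or lowest library to the nearest other was divided by the range of all 5 (Dixon's test). The test covered 244 groups of values, of which chance alone would pick about 12. It picked 42, and 32 of these were vesicle 1. LPS libraries, of which there were 3, were not tested.

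Vesicle 1 had the lowest total, 43611478 counts, the lowest TMM factor, 0.728 against at least 1.06, and 2.54% of its counts in the translation factor Eif3a against at most 0.657% in the other vesicle libraries. It was highest for Irs2 (176 CPM against at most 14.3), Il17f (23.0 CPM), Tbkbp1 (19 CPM), Slc8a2 (18.1 CPM), Taf9b (17.3 CPM), Mss51 (14.5 CPM), Nid2 (10.8 CPM), Nfkb2 (477 CPM), Pik3ca (82.2 CPM), Slfn9 (355 CPM), Tab2 (182 CPM) and U2surp (781 CPM). It was lowest for the tRNA synthetases Yars (85.5 CPM) and Eprs (622 CPM), the division genes Bub1b (117 CPM) and Mcm2 (217 CPM), the respiratory genes Cyc1 (10.5 CPM) and Ndufb10 (25.7 CPM), and the sterol gene Pmvk (12 CPM). It was also lowest for Ei24 (8.07 CPM), Dcp1b (0.413 CPM), Mutyh (0.504 CPM), Glrx5 (5.37 CPM), Il1r1 (6.56 CPM), Lamc1 (189 CPM), Lcn2 (12.3 CPM), Pdgfrb (6.51 CPM), Taldo1 (20.4 CPM) and Xiap (61.5 CPM).

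Among control libraries, control 3 was highest for U2surp (221 CPM) and Rptn (0.0685 CPM), control 4 for Cyc1 (41.0 CPM) and Mutyh (4.09 CPM), control 2 for Calml3 (0.0290 CPM) and control 5 for Krt4 (0.0639 CPM). Among vesicle libraries, vesicle 2 was highest for Dmkn (0.0301 CPM), vesicle 4 for Tnnt3 (0.0813 CPM) and vesicle 5 for Igfbp5 (0.0333 CPM), while vesicle 4 had the lowest share of even numbers among counts of 1 to 19, 69.7%. The values under 0.1 CPM come from genes at 0 in the other libraries of the group.

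The 122 genes called between vesicles and control followed GC content: higher genes had a median of 40.7% and lower genes 57.1%. Vesicle 1 alone is argued against, since all 122 genes stayed called in the same direction without it, with 882 calls in all. A GC or length trend between libraries may account for much of the pattern: with an offset 1 of the 122 genes stayed past the threshold, as the median absolute log2 fold change went from 0.90 to 0.59 and the median SE from 0.156 to 0.161, so that calls ended because the folds shrank. What stays open is the rest, since genes that respond together can share a GC content. All 122 kept their sign, but they were chosen on these same libraries, which makes this likely in advance. With the offset and the library set as a term 118 stayed called, but those p-values measure only the small spread between close libraries. With close libraries summed 0 of the 122 were called. A response to the vesicles was not tested apart from this trend.

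Of 100 splits of the control and vesicle libraries, 2 gave at least as many calls as the real 122, the real split and 1 other. The other, with 449 calls, is control 1, 3 and 4 with vesicle 2 and 3 against the rest and points to a structure of the libraries. Such splits do not exclude chance, since close libraries may not be independent replicates. With close libraries summed 0 genes were called.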

How the results depend on the processing

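Effective counts, the GC and length offset, the library sets, the summing of close libraries and the splits of LPS libraries were chosen after seeing the data; all other alternatives were planned, and the cause of a change was not tested unless given.

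LPS vs control had 3293 higher and 5294 lower genes, and vesicles vs LPS 5705 and 3435. RLE and upper-quartile scaling, DESeq2, voom, no filter, only the groups compared, the replicate block, library size without the top genes, the GC offset and the fold threshold kept each of these numbers within 1.5 times, and leaving out 1 library gave 2832 to 4157 and 4741 to 6324, then 5281 to 6190 and 3064 to 4197. Upper-quartile scaling moved the median log2 fold change of all genes in LPS vs control from -0.249 to -0.142. It moved the other way with the replicate block (-0.396), voom weights (-0.51) and no filter (-0.685). The strict filter, which tests 13586 genes, left 3041 lower and 3391 higher. Effective counts, which test fewer genes at lower depth, gave 2135, 2812, 3192 and 2234. Summing close libraries, which leaves fewer replicates, gave 1013, 2506, 4083 and 1746.

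Vesicles vs control had 83 higher and 39 lower genes. Higher and lower genes were 558 and 320 with DESeq2, 3176 and 3299 with voom weights, 46 and 23 with no filter, 138 and 75 with only the 2 groups compared, 290 and 129 with effective counts, 0 and 1 with the GC offset (smallest adjusted p 0.037; 1498 genes at an unadjusted p), 0 and 0 with the GC offset and replicate block, 0 and 0 with close libraries summed (smallest adjusted p 1; 466 genes at an unadjusted p), 3414 and 3293 in the first set, 3525 and 4031 in the second, 2977 and 3305 with a set term, and 1777 and 2779 with set term and offset. The strict filter gave 144 higher and the fold threshold 21, while RLE, upper-quartile scaling and library size without the top genes kept both numbers within 1.5 times. Leaving out 1 library gave 25 to 510 and 7 to 372. The replicate block gave 8 and 2. The numbers do not pair the libraries: control and vesicle libraries of the same number correlated from -0.302 to 0.336, with 2 of 5 over 0.1.

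Genes opposite in both LPS comparisons were 7498. They were 4226 on effective counts, 3323 with close libraries summed and, with LPS libraries split, 4167, 4271, 4295, 4410, 4479 and 4470, over fewer libraries; leaving out 1 library gave 6764 to 9209.

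Gene lists called were 10, 12 and 9. With effective counts they were 9, 9 and 8, with the GC offset 10, 10 and 6, with the replicate block 9, 10 and 8 and with close libraries summed 10, 12 and 7. With an estimated correlation they were 2, 1 and 0, with fry in either direction 30, 30 and 5, with directional fry 4 in vesicles vs control, and without 1 library 8 to 10, 10 to 12 and 6 to 13. In LPS vs control, effective counts ended the apoptosis (adjusted p = 0.47) and TGF-beta (0.19) calls and made one of unfolded protein response genes (0.0044), and the GC offset ended that of apoptosis (0.095) and made one of oxidative phosphorylation (0.0036, and 0.0085 with block). The block ended that of apoptosis (0.054), and block with offset those of apoptosis (0.095) and TGF-beta (0.053). In vesicles vs LPS, effective counts ended the calls of apoptosis (0.45), NRF2 (0.25), oxidative phosphorylation (0.11) and TGF-beta (0.23) and made that of unfolded protein response genes (0.00079). The GC offset (0.086 and 0.10), the block (0.054 and 0.066) and both together (0.094 and 0.16) ended those of apoptosis and TGF-beta. In vesicles vs control, the ribosomal call ended with effective counts (0.11), the offset (0.47) and offset with block (0.56), that of G2/M with the offset (0.14) and offset with block (0.14), that of unfolded protein response genes with the block (0.068), and those of ribosomal (0.60) and unfolded protein response genes (0.065) with close libraries summed. The mitochondrially encoded list in vesicles vs control turned downward with the GC offset (adjusted p = 0.41, and 0.37 with replicate block), and Trp53 turned to -0.25 within the second set.

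Among named genes, the block weakened 20 and effective counts 14 calls, the GC offset 21, summing close libraries 30 and leaving out a library 122 over all libraries. Depth limits the LPS comparisons to genes above 1.69 CPM where LPS libraries have no count.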

Other observations

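The tests of effective counts, of the NF-kB list as a cause, of whole cells or tissue and of the library sets were chosen after the result was seen, and the marker lists for epithelium, muscle and other sources were written after many of their genes had been displayed; the tests of RNA selection, of reads from another library and of other splits were set before their results.

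Other gene lists held members called between LPS and control libraries, without passing camera on deposited counts. Of 19 tested replication-dependent histone genes, 6 were higher in LPS than in control libraries and 4 lower (adjusted p = 0.53), with Hist2h2ac and Hist1h1b the largest rises, at log2 fold changes of 4.81 and 3.45. Of 8 nuclear-retained noncoding RNAs, Malat1, Gas5 and Snhg1 were lower, Malat1 by a log2 fold change of -2.48, and Xist was higher (adjusted p = 0.60). Of 18 circadian clock genes, Arntl, Per1, Cry2, Nfil3 and Ciart were lower and Clock and Dbp higher (adjusted p = 0.73). Of 23 unfolded protein response chaperones, 11 were lower and Edem1 was higher (adjusted p = 0.26, and 0.0044 on effective counts), and of 22 heat shock genes 9 were lower and Hspa8 and Cryab higher (adjusted p = 0.60). Of 30 hypoxia and glycolysis genes, Hk2, Pfkfb3, Aldoc and Vegfa were lower and Egln1 and Egln3 higher (adjusted p = 0.78). These are calls on deposited counts, and genes named here outside the fixed rule were chosen after their values were seen.

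Markers of other brain cell types were sparse and mixed. In LPS against control libraries, 3 of 15 tested neuronal markers were higher, Syp, Camk2a and Bdnf, and Slc17a7 was lower (camera adjusted p = 0.34). Gfap was higher and Slc1a2, Slc1a3 and Aldoc lower among 8 astrocyte markers (adjusted p = 0.40), Cd68 was lower among 7 microglial markers (adjusted p = 0.93), and Mog lower among 5 oligodendrocyte markers (adjusted p = 0.94). Between vesicle and control libraries the camera adjusted p of these lists ranged from 0.49 to 0.97.

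LPS libraries differed from control in 8587 and from vesicle libraries in 9140 genes. Sampling noise from few distinct molecules is argued against as the whole cause, since 4947 genes were still called against control on effective counts. Simulated noise gave at most 0 there. Sampling noise may account for part, since the planned test called a median of 1690 genes from simulated noise alone, which was larger than measured. Another RNA selection stays open. The share of counts in small nuclear and nucleolar RNAs was 0.985 times that of the other libraries. They held only 0.0174% to 0.0207% of the counts in LPS libraries, which is too little to decide. Mitochondrial ribosomal RNA, at 1.59% against 0.0242% in control, goes the other way, and no label tells the kits of single libraries apart. A response to LPS through NF-kB stays open, since the list had a camera adjusted p of 0.60 with members going both ways. LPS exposure itself, and any batch shared by the LPS libraries alone, cannot be told apart by this design.

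Some squamous epithelium and skeletal muscle transcripts stood out in the LPS libraries. Of 35 epithelial markers 15, and of 27 muscle markers 10, were specific to them, meaning at least 1 CPM and at least 10 times the mean of either other group, as were 2 of 11 cardiac markers, against 0 of the 15 hepatocyte, 9 erythroid, 13 lymphocyte and 13 intestinal markers. Whole cells or tissue stay open. Of 10 abundant genes of these types 1, Perp at 67.4 CPM, lay above its reference level, and Perp was at 25.5 CPM in control libraries. Krt5, Krt14 and Krt6a were at 1.48, 0.772 and 0 CPM and Sfn at 21.9, beside Krt4 at 31.9 and Krt13 at 64.6. Acta1, Ckm, Mylpf, Tnnc2 and Myl1 were at 3.99, 1.41, 1.76, 7.50 and 1.59 CPM beside Myh1 at 29.1 and Myh8 at 62.9. These values cannot decide, since the reference genes were chosen after their values were seen. Krt4, Myh1 and Myh8 are among the largest rises, and CPM is not scaled to gene length. Reads from another library of such tissue would bring the same abundant genes, so that these values cannot decide that source either. Reads from a library of another makeup may be a source. The specific epithelial and muscle markers had median variance-to-mean ratios of 2.19 and 4.38 over the LPS libraries. These are medians over single genes, which the 41.3 of library pairs is not, and no such median was taken over other genes. Ppl, Ryr1 and Trp63, also specific, had ratios of 111, 129 and 52.8. Only 2 of the specific markers, 1 of each type, had not been displayed before the lists were written, which is too few to decide.

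Of 56 splits of the 8 libraries compared, 1, the real one, gave as many genes as the 8587 of LPS vs control (highest other 233), and 1 gave as many as the 9140 of vesicles vs LPS (highest other 688). This would exclude chance only if each library were an independent replicate. Control and vesicle libraries include close ones, for which that was not decided. As many gene lists or more were called in 12 of 56 splits for LPS vs control (10 real, highest other 12). For vesicles vs LPS it was 20 of 56 (12 real, highest other 16). Other splits can keep all or most LPS libraries on 1 side, as control 1, 2 and 5 against the rest, with 12 lists in LPS vs control. Such splits still hold the difference of the LPS libraries, so that these numbers cannot decide on chance. For vesicles vs control 71 of 100 splits gave as many lists or more (9 real, highest other 16), and the number called cannot be separated from chance.

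With the library set as a term and vesicle 1 left out, 6282 genes were called between vesicle and control libraries. Of 49 shufflings of the group labels within the same scheme, the median gave 0 calls, 1 gave as many, and the highest was 6395. Single libraries were shuffled, which mostly parts close libraries that the real groups keep together, so that these numbers do not measure chance. With close libraries summed 0 genes were called. Within the second set Trp53 was lower in vesicle libraries (log2 fold change -0.25, adjusted p = 0.00033) and within the first higher (0.31, adjusted p = 0.0022), a difference that was not tested.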
